A study of Rattus norvegicus with 72 samples.

How the data were processed

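Liver expression was measured on 72 two-colour Agilent arrays from 36 rats that had been given acetaminophen in methyl cellulose by oral gavage. The rats fall into 12 groups of 3, at 50, 150, 1500 or 2000 mg/kg and at 6, 24 or 48 h. The unit mg/kg is written out in the titles of the 150 mg/kg groups at 6 h and 24 h only, and the other titles give mg. Each rat was a separate animal, and its RNA, from the left liver lobe, was hybridised against a pool of RNA from vehicle-treated control rats of the same dose and time series. The titles name such a pool for 10 groups. For 150 mg/kg they name a mock control liver at 6 h, and at 24 h a sham control on one array of each rat and a mock control liver on the other. These were taken as pools from the protocol, and a difference between the controls of that 24 h group would stay in its means. Each rat was run on 2 arrays with the dyes exchanged.

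The authors deposited log10 ratios, 1 column for each array, made with Agilent G2566AA Feature Extraction software from a G2565AA scanner, per the labels. Version, settings and the normalization within arrays are not given in the sources used here. The deposited log10 values were capped at 2 in either direction, and 23 values stood at that cap. Column medians lay between -0.0191 and 0.019 and standard deviations between 0.0654 and 0.276, so the columns were centred, by an unknown method. Scale was read from the cap and from the software, which writes log10 ratios. The direction, red over green, is not stated in the labels and is likely from the convention of that software. If it were green over red, every sign given here would turn. The 2 arrays of a rat correlated negatively where changes were large, which shows that a fixed direction was used there and does not tell which. In the 1500 and 2000 mg/kg rats at 48 h this correlation was between -0.718 and -0.482, and over all 36 rats it was below 0 in 21. After removal of each probe's mean over both orientations it was below 0 in 29 of 36. The standard deviation over probes of that dye effect was 0.238 on the log2 scale, and the part that is equal on both arrays of a rat cancels in their mean. A part that differs in strength between them can remain. Arrays of a group in the same orientation correlated at 0.0937 or above, and 0 pairs of arrays held identical values. Missing values made up 0.211% of the table, 1 to 373 probes on an array, and 2.68% of values were exactly 0. Signal intensities were not used here, so probe brightness is unknown.

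Ratios were converted to log2, turned so that a positive value means more RNA in the treated rat than in its pool, and averaged over the 2 arrays of a rat, both of which were required. Of 20500 probes, 12750 carried 1 gene symbol in the platform annotation, 5 carried several and 7745 carried none. The Entrez identifiers of 12720 probes were found in the current rat gene table (assembly GRCr8), and 0 symbols changed on update. Probes of the same symbol were averaged, which applied to 2266 of 9653 genes, and a probe with several symbols or none was kept as a single unnamed probe. A gene needed values from at least 2 rats in every group, which left 17299 of 17403 features, 9606 of them with a symbol. Genes are counted below as features of this kind. No named gene had probes of opposite sign beyond 1.5-fold in the comparison of dose levels. In size, probes of a gene differed by up to log2 3.01, for Inmt at 48 h (-5.19 to -2.18), and by over log2 1 for Acsl1, Aen, Inmt and Papss1 at 24 h, Papss1 at 48 h and Cdkn1a at 6 h, so that their means stand for unlike probes.

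The 12 group means were fitted in one linear model over all 36 rats with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation (residual degrees of freedom 24, prior degrees of freedom 3.277). Each group mean was tested against 0. Further contrasts set the mean of 1500 and 2000 mg/kg against the mean of 50 and 150 mg/kg at each time, 2000 against 1500 mg/kg at each time, and 24 against 6 h and 48 against 24 h over 1500 and 2000 mg/kg. The differences between these contrasts were tested as interaction terms. A gene was called at a Benjamini-Hochberg adjusted p below 0.05 together with a change of at least 1.5-fold. Adjusted p-values in the text are from limma and are two-sided. The pool was taken as 1 control sample for each dose and time. The p-values therefore leave out the spread between control rats, and a difference between pools enters every contrast between doses or times. Values are means on the log2 scale with the standard deviation (SD) between rats for groups and the standard error (SE) of the model for contrasts. Fold changes are back-transformed log2 values.

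A set of 32 gene lists was written before the data were examined, 23 of pathways and 9 of cell type markers. They were tested with camera, which compares a list with all other genes, with an inter-gene correlation preset at 0.01 and again with an estimated correlation, and p-values were adjusted over the 32 lists. Missing rat values, in 1767 features, were filled with the group mean for these tests only. The test fry, which does not compare a list with other genes, was run too.

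The genes named were chosen by a rule set at the same stage, among symbols other than provisional names. It took the 6 highest and 6 lowest genes called with the same sign on all 6 arrays in each 1500 and 2000 mg/kg group, and the 2 highest and 2 lowest in each lower group. It also took the 6 highest and 6 lowest called in each contrast. From each list and time it took up to 4 called members with the largest change between dose levels, or the member with the smallest adjusted p where none was called. A further 20 genes were followed in every group, of which Gclc, Cyp7a1, Hspa1b, Ccnd1 and Alb were not measured here. Genes named outside this rule are marked as chosen after their values were seen.

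The procedure was tested on simulated data with known changes in 17299 genes. At 24 h, 96% of genes changed 2-fold and 36% of those changed 1.5-fold were called for 2000 mg/kg, with 3 unchanged genes. For dose levels the values were 98%, 42% and 4, and for 2000 against 1500 mg/kg 84%, 28% and 5. The simulation left out differences between control pools and in spread between groups, as do these counts. Alternatives covered centring and scaling of arrays, the 72 arrays as observations with the rat as a random block (statmod 1.5.0), the compared rats alone, no fold minimum, robust moderation, a filter on probes at exactly 0 on over 50% of arrays, probes with a value on all arrays, single probes, the dose-and-time group as a random block, and each rat left out. Removal of the remaining dye effect, removal of an expression axis shared by some lower-dose groups or of that of the 150 mg/kg groups, each lower dose alone as the lower arm, and all alternatives for interaction terms were added after the data were seen. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9. Scan dates and slides were not used here, so no technical batch was tested.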

Results

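Gene expression was measured in the liver of 36 rats given acetaminophen, a drug that injures the liver at high dose, and in pools of RNA from rats given the vehicle alone. The 12 groups of 3 rats cover 50, 150, 1500 and 2000 mg/kg at 6, 24 and 48 h. Each rat was compared with the control of its own dose and time on 2 arrays with exchanged dyes, so that a value is a ratio of 1 rat to that control. The titles call this control a pool, except for 150 mg/kg at 6 h (a mock control) and 24 h (sham and mock controls). Every sign below rests on the convention of the array software, red over green, which the labels do not state. The labels state a design of single treated animals against pooled controls, which the comparisons follow. Of 17299 genes tested, the number called in a group ranged from 6 to 3802. More genes were called at 50 than at 150 mg/kg at each time, with 246 and 6 at 6 h, 614 and 25 at 24 h, and 684 and 256 at 48 h. Without a fold minimum the counts of all comparisons but 150 mg/kg at 6 h were over 1.5 times as large, between 51 and 9793, and at 1500 and 2000 mg/kg 46.4 to 53.4% were higher, against 58.3 to 72.2% with it.

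**Figure D1:**
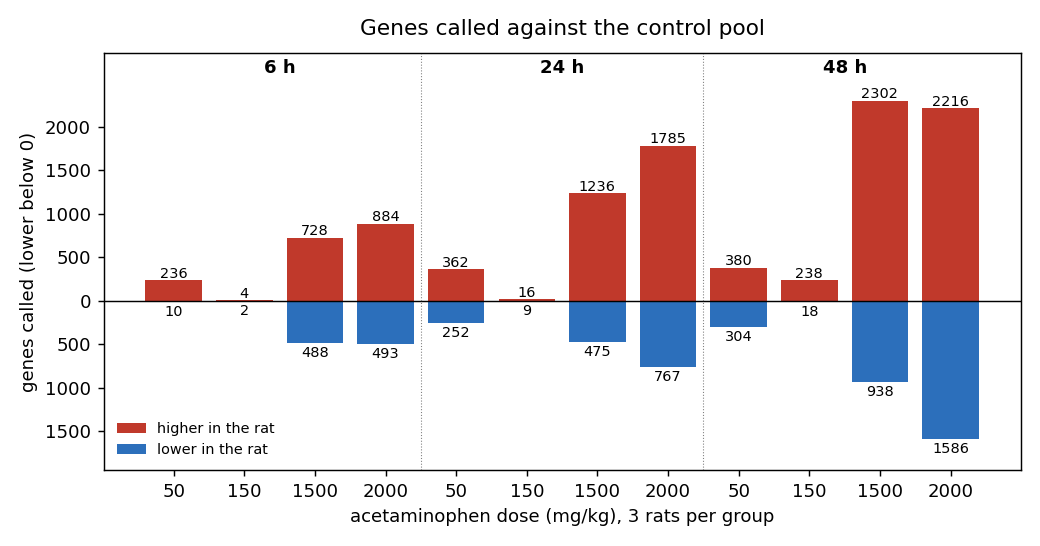
Genes called higher and lower than the control pool (number of genes) in each of the 12 groups, by dose in mg/kg and time in h. The number was highest at 2000 mg/kg and 48 h, with 2216 genes higher and 1586 lower, but not without a fold minimum (9793 at 1500 and 9375 at 2000 mg/kg) or without rat 3119 (2877, against 3240 at 1500 mg/kg).

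At 6 h after 50 mg/kg, Zfp354a was 4.1-fold higher than in the pool (log2 2.03 ± 0.57, mean ± SD, n = 3, limma adjusted p = 4.11e-05). Usp7 was 3.33-fold higher (log2 1.74 ± 0.14, adjusted p = 2.04e-07). Ldhc was 2.12-fold lower, and Irs3 was 1.65-fold lower. Of 246 genes called, 236 were higher. With arrays scaled to equal spread the total was 562, of which 464 were higher and 98 lower. At 6 h after 150 mg/kg, the metal-binding metallothioneins Mt2A and Mt1 were 7.82-fold and 3.64-fold higher (log2 2.97 ± 0.49 and 1.86 ± 0.29), and Chka was 1.63-fold lower. Chosen after their values were seen, Nploc4 and Dbil5 were the other two of 4 genes called higher, at log2 1.12 and 0.96, and the second of 2 called lower was a probe without a symbol. With scaled arrays 474 genes were called at 150 mg/kg, 202 higher and 272 lower. With the rats as 72 arrays the count was 51, and with an axis of expression shared by some lower-dose groups removed it was 13. Fitted on their 3 rats alone, the 6 calls ended, with 0 called by limma and 3789 genes at an unadjusted p below 0.05. Without rat 3081, 3082 or 3083 the count was 1, 2 or 1. The call of Mt1 ended without rat 3081 or 3083 (log2 1.83 and 1.74), and that of Chka without any of the 3 (log2 -0.80, -0.65 and -0.68). That of Ldhc at 50 mg/kg ended with its 3 rats alone.

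At 150 mg/kg and 6 h, 4 genes were called higher and 2 lower in the fit over all groups, too few to test how many calls the lower doses shared, and 1374 genes had an unadjusted p below 0.05. Of 20 measured genes of cholesterol synthesis, 0 were called at 150 mg/kg by limma, 1 was lower adjusted over the list alone, and 15 had an unadjusted p below 0.05. Their median was log2 -0.37 (camera adjusted p = 4.99e-13), and the call was lost at adjusted p = 0.235 with an estimated correlation. Hmox1, the heme oxygenase of the antioxidant response, was not called at either dose, with log2 0.15 ± 0.11 at 50 mg/kg and 0.06 ± 0.12 at 150 mg/kg (SD, n = 3).

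At 6 h after 1500 mg/kg, Zfp354a was 24.6-fold higher (log2 4.62 ± 0.12, SD, n = 3, adjusted p = 6.09e-12) and Retreg1 was 9.96-fold higher (log2 3.32 ± 0.15). Igfbp1 was 7.02-fold higher. The amino acid enzymes Got1, cytosolic aspartate aminotransferase, and Sds, serine dehydratase, were 6.11-fold and 6.09-fold higher, and Mt1 was 6.84-fold higher. Nrep, Rgs3, the kinase gene Sgk1, Gimd1, Amacr and Oaf were lower, from 6.88-fold for Nrep (log2 -2.78 ± 0.44) to 3.67-fold for Amacr, a racemase of bile acid synthesis. After 2000 mg/kg, Mt2A and Mt1 were 23.7-fold and 23.2-fold higher (log2 4.57 ± 0.14 and 4.54 ± 0.09). Retreg1, Zfp354a, Sds and Got1 were 15.6-fold, 14.4-fold, 12.6-fold and 12.1-fold higher. Nrep was 9.98-fold lower (log2 -3.32 ± 0.43), and Gimd1, Erich1, Akirin2, Amacr and Sgk1 were between 5.73-fold and 4.59-fold lower. The rule required the same sign on all 6 arrays.

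Cdkn1a, the p21 inhibitor of the cell cycle, was 2.32-fold and 2-fold higher at 6 h after 1500 and 2000 mg/kg, and Mt2A was 5.54-fold higher after 1500 mg/kg. A2m, a macroglobulin of the acute phase in the rat, was 5.52-fold and 4.87-fold higher, and Hmox1 was 2.16-fold and 3.79-fold higher. Some of these calls ended when 1 rat was left out. Without rat 3032 that of A2m ended at 1500 mg/kg (log2 2.08, adjusted p = 0.066), and without rat 3095 at 2000 mg/kg (log2 1.86, adjusted p = 0.0538), with the change still over 1.5-fold. Those of Hmox1 ended without rat 3030 or 3032 (log2 0.52 and 1.31) and without rat 3094 (log2 1.17), and that of Ddit3, a transcription factor of the stress response, 1.81-fold higher at 2000 mg/kg, ended without rat 3094 (log2 0.21). In all, 1216 genes were called at 1500 mg/kg, 728 higher and 488 lower (2489 and 2555 without a fold minimum), and 1377 at 2000 mg/kg, 884 higher and 493 lower (554 and 525 with the shared axis removed). Called at both doses in the same direction were 447 genes higher, against 37.2 expected, and 198 lower, against 13.9. The count at 1500 mg/kg was 493 without rat 3032 and 2438 without rat 3030. It was 600 with arrays scaled to equal spread, 800 with the shared axis removed and 59 with its 3 rats fitted alone, where the calls of Igfbp1, Gimd1, Mt2A, Hmox1 and A2m ended. At 2000 mg/kg scaled arrays gave 903, and the 3 rats alone ended the calls of Hmox1 and Ddit3.

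At 24 h after 50 mg/kg, Rup2 and Pnrc2, a nuclear receptor coactivator, were 2.53-fold and 2.38-fold higher (log2 1.34 ± 0.25 and 1.25 ± 0.29, SD, n = 3), and Sgk1 and Slc25a25, a mitochondrial carrier, were 2.89-fold and 2.49-fold lower. Of 28 measured genes of coagulation and complement made by hepatocytes, 5 rose, also adjusted over the list alone (camera adjusted p = 2.81e-06), but the call was lost at adjusted p = 0.97 with an estimated correlation. Of 614 genes called, 362 were higher and 252 lower. The count was 54 with the shared axis of expression removed, which ended the calls of Rup2 and Pnrc2, and 116 with the axis of the 150 mg/kg groups removed. Fitted on their 3 rats alone, 0 were called by limma, with 4515 at an unadjusted p below 0.05. It was 399 without rat 3137, where that of Rup2 ended (log2 1.20), and 913 without rat 3138.

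At 24 h after 150 mg/kg, Zfp354a was 3.65-fold higher (log2 1.87 ± 0.85, SD, n = 3) and Klf9, a transcription factor induced by glucocorticoids, was 2.17-fold higher. Pbsn, the androgen-dependent gene of probasin, was 5.74-fold lower (log2 -2.52 ± 0.51) and Car7 was 1.98-fold lower. Chosen after their values were seen, Klf9 and Cyp4a3 and a probe without a symbol were the 3 genes called higher at both 50 and 150 mg/kg, against 0.335 expected. Of 27 measured macrophage and monocyte markers 1 fell, and 2 adjusted over the list alone (median log2 -0.26, camera adjusted p = 6.87e-11), with the list call lost at adjusted p = 0.144 with an estimated correlation. Of 25 genes called, 16 were higher and 9 lower, while with arrays scaled to equal spread 565 were called, 186 higher and 379 lower. The count was 4 with the 3 rats fitted alone and 59 with their arrays as observations. It was 3 without rat 3070, 4 without rat 3074 and 12 without rat 3069. Without rat 3074 the calls of Zfp354a (log2 1.53), Klf9 (log2 0.76), Pbsn (log2 -2.40) and Car7 (log2 -0.90) ended, and without rat 3070 those of Zfp354a (log2 1.72) and Pbsn (log2 -2.35).

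At 24 h after 1500 mg/kg, Akr7a3 was 19.9-fold higher (log2 4.32 ± 0.35, SD, n = 3, adjusted p = 9.05e-12). Mt2A and Mt1 were 17.1-fold and 11.4-fold higher, Hspa1a, an inducible heat shock protein, was 11.7-fold higher (log2 3.55 ± 1.65), and Phgdh, the enzyme of the first step of serine synthesis, was 8.29-fold higher. Atf3, a transcription factor of the stress response, was 6.92-fold higher, with a wide spread (log2 2.79 ± 2.09). Stac3 was 17.6-fold lower (log2 -4.13 ± 0.50) and Nrep 15.3-fold lower. Fads1, a desaturase of polyunsaturated fatty acids, Sez6, Cyp3a2 and Bmf, a pro-apoptotic gene, were between 8.98-fold and 5-fold lower. After 2000 mg/kg, Mt2A was 26.2-fold higher (log2 4.71 ± 0.20), Hspa1a 25-fold, Atf3 19.5-fold, Mt1 17.2-fold, Akr7a3 16.4-fold and Zfand2a 12.5-fold. Nrep and Stac3 were 17.4-fold and 17.1-fold lower. Sez6, Fads1, the fatty acid synthase Fasn and G6pc1, the glucose-releasing phosphatase, were between 10.4-fold and 6.66-fold lower.

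Nqo1, a quinone reductase of the antioxidant response, was 4.55-fold and 5.96-fold higher at 24 h after 1500 and 2000 mg/kg (log2 2.19 ± 0.16 and 2.58 ± 0.22), and Gsta3, a glutathione transferase, was 6.8-fold and 4.85-fold higher. Glul, glutamine synthetase of pericentral hepatocytes, was 3.14-fold and 2.76-fold lower, and Cyp1a2 was 2.76-fold and 1.72-fold lower. Cyp2e1, a P450 that oxidises acetaminophen, was not called, at log2 0.10 ± 0.42 and 0.51 ± 0.63. Hmox1 was 2.74-fold and 6.91-fold higher, Ddit3 2.31-fold and 3.64-fold, Myc 1.73-fold and 2.15-fold, A2m 5.33-fold and 10.5-fold, and Lcn2, a neutrophil and acute phase protein, 1.83-fold and 2.57-fold. At 1500 mg/kg rat 3019 decided 3 of these. Without it A2m was log2 0.94 and Lcn2 was log2 -0.02, neither called, and the call of Hmox1 ended at log2 1.19, as it did without rat 3018 (log2 0.93). At 2000 mg/kg those of Cyp1a2 and Lcn2 ended without rat 3106 (log2 -0.63 and 0.95). Called at 1500 mg/kg were 1711 genes, 1236 higher and 475 lower (3169 and 3127 without a fold minimum), and at 2000 mg/kg 2552, 1785 higher and 767 lower (4162 and 3961). Both doses shared 851 genes higher, against 127.5 expected, and 293 lower, against 21.1. With arrays scaled to equal spread the counts were 940 and 1149, and the calls of Hmox1 and Lcn2 at 1500 mg/kg and of Cyp1a2 at 2000 mg/kg ended. With the 3 rats of 1500 mg/kg alone those of Atf3, Cyp3a2, Hmox1, Ddit3, Lcn2 and A2m ended.

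At 48 h after 50 mg/kg, the growth arrest genes Gadd45g and Gadd45a were 3.08-fold and 2.35-fold higher (log2 1.62 ± 0.62 and 1.23 ± 0.78, SD, n = 3), and Zfp354a and Irf2bpl were 2.56-fold and 2.14-fold lower. After 150 mg/kg, Zfp354a was 2.91-fold higher (log2 1.54 ± 0.35) and Tmem70 2.22-fold higher, while Mt2A and Mt1 were 3.03-fold and 2.01-fold lower. Of 30 measured genes of fatty acid oxidation, 4 rose at 150 mg/kg, and 5 adjusted over the list alone (camera adjusted p = 2.2e-05), with the call lost at adjusted p = 0.787 with an estimated correlation. At 50 mg/kg 684 genes were called, 380 higher and 304 lower, and at 150 mg/kg 256, 238 higher and 18 lower. With the residual dye effect removed the counts at 50 mg/kg were 371 higher and 157 lower. Both doses shared 105 genes higher, against 5.23 expected. Of the genes called at 50 mg/kg at 24 h, 146 higher and 143 lower were called alike at 48 h, against 7.95 and 4.43 expected. With the shared axis removed the counts were 43 and 43, with 18 higher and 25 lower at 50 mg/kg, and the calls of Gadd45g, Gadd45a, Irf2bpl and Mt1 ended. With the axis of the 150 mg/kg groups removed 152 were called at 50 mg/kg, 62 higher and 90 lower, and the call of Irf2bpl ended (log2 -0.52). With the 3 rats of a group alone limma called 0 at either dose, with 4928 and 4394 genes at an unadjusted p below 0.05. At 150 mg/kg 551 were called with scaled arrays and 141 without rat 3059. The calls of Zfp354a and Mt2A at 150 mg/kg ended without that rat (log2 1.34 and -1.52), and that of Mt1 without rat 3057, 3058 or 3059 (log2 -0.98, -1.06 and -0.98). At 50 mg/kg that of Irf2bpl ended without rat 3149 or 3151 (log2 -1.21 and -0.85), and that of Gadd45a without rat 3151 (log2 0.78).

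At 48 h after 1500 mg/kg, Spp1, which encodes osteopontin, and A2m were at least 80.6-fold and 72.9-fold higher (log2 6.33 ± 0.54 and 6.19 ± 0.47, SD, n = 3). These are lower bounds, since 4 of 6 arrays for Spp1 and 2 of 6 for A2m stood at the cap. Gpnmb, a glycoprotein of macrophages, was 17.8-fold higher. Mcm5, a subunit of the replicative helicase, S100a10 and Ube2c were 13.6-fold, 13.4-fold and 10.6-fold higher. Stac3 was 17.6-fold lower (log2 -4.14 ± 0.15) and Zfp354a 12.6-fold lower. Cyp2c11, the male-specific P450 of rat liver, Pbsn, Serpina3c and Cyp3a2 were between 11.2-fold and 8.24-fold lower. After 2000 mg/kg, Spp1 and A2m were 37.3-fold and 23.7-fold higher, and Ska1, Gstp1, Gsta3 and the mitotic kinase Cdk1 were 15.4-fold, 13.8-fold, 13.2-fold and 12.2-fold higher. Stac3 was 22.9-fold lower (log2 -4.52 ± 0.27), and Nrep, Pbsn, Cyp3a2, Cyp2c11 and Inmt were between 15.8-fold and 9.45-fold lower.

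At 48 h after 1500 and 2000 mg/kg, Cyp2e1 was 4.73-fold and 2.16-fold lower (log2 -2.24 ± 0.45 and -1.11 ± 0.68), Cyp1a2 was 4.23-fold and 3.94-fold lower, and Glul 2.29-fold and 3.37-fold lower. Nqo1 was 2.62-fold and 5.4-fold higher, Mt2A 10.4-fold and 7.28-fold, Atf3 3.09-fold and 7.69-fold, and Lcn2 3.5-fold and 2.56-fold. Cdk1 was 7.29-fold higher after 1500 mg/kg. Hmox1 was 3.39-fold and 2.23-fold higher, with the call at 2000 mg/kg ended by scaled arrays or without rat 3117 or 3119 (log2 1.18 and 1.01). Gsta3 was 2.1-fold higher at 1500 mg/kg, which ended without rat 3006 (log2 0.40) and with the 3 rats alone. At 1500 mg/kg 3240 genes were called, 2302 higher and 938 lower (4541 and 5252 without a fold minimum), and at 2000 mg/kg 3802. Both doses shared 1608 genes higher, against 294.9 expected, and 611 lower, against 86. With arrays scaled to equal spread the counts were 1923 and 2447, and with the shared axis removed 2124 and 2243.

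**Figure D2:**
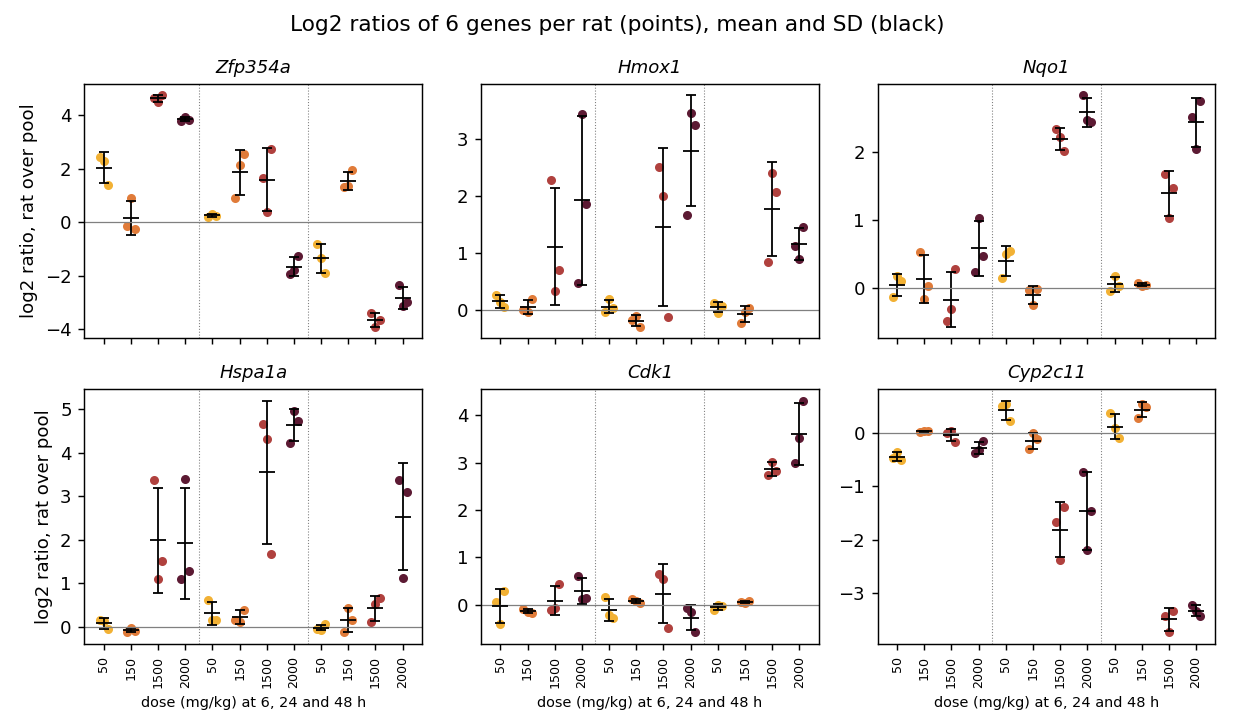
Change from the control pool (log2) of Zfp354a, Hmox1, Nqo1, Hspa1a, Cdk1 and Cyp2c11 in each of 36 rats (points) with the group mean (line), by dose in mg/kg and time in h. Zfp354a was higher than the pool at 6 h and lower at 48 h after 1500 mg/kg, with group means of log2 4.62 and -3.65.

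The dose levels were compared at each time as the mean of 1500 and 2000 mg/kg minus the mean of 50 and 150 mg/kg, which asks which genes differ between high and low doses. At 6 h, the immediate early transcription factor Egr1 rose 11-fold (log2 3.46 ± 0.41, SE, n = 6 rats at each level, limma adjusted p = 4.43e-07). Retreg1 rose 9.67-fold (log2 3.27 ± 0.19), and Igfbp1, Zfp354a, Got1 and Sds rose between 9.25-fold and 8.63-fold. Nrep fell 8.94-fold (log2 -3.16 ± 0.28) and Amacr 5.04-fold, and Fxyd7, Gimd1, Akirin2 and Erich1 fell between 4.52-fold and 3.81-fold. Of 1406 genes called, 808 rose and 598 fell. The balance reversed without a fold minimum (2821 and 2854) and against 50 mg/kg alone (710 and 770). The count was 932 with the dose-and-time group as a random block and 807 with the shared axis removed, 382 higher and 425 lower. Counts of list members adjusted over the list alone are given where they differ from those over all genes.

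Of 34 measured genes of the urea cycle and amino acid breakdown, 7 rose and 1 fell at 6 h (camera adjusted p = 0.0112). They included Sds, Tat, the aminotransferase of tyrosine, 4.58-fold, Tdo2, the dioxygenase of tryptophan, 2.92-fold, and Oat, an aminotransferase of ornithine, 1.91-fold. Of 30 genes of fatty acid oxidation and targets of PPARA 5 rose (camera adjusted p = 0.00322). Among these were Cidea, 2.73-fold, and the carnitine acyltransferases Crat and Cpt2, 1.93-fold and 1.77-fold. Of 23 genes of ribosome biogenesis 2 rose, Nip7 and Tsr1, 1.85-fold and 1.8-fold (adjusted p = 0.0218). Of 44 genes of oxidative phosphorylation limma called 0 at 1.5-fold, while 30 were higher at any fold size and 32 had an unadjusted p below 0.05 (median log2 0.26, camera adjusted p = 5.94e-10). Sdhd, a subunit of succinate dehydrogenase, was closest at 1.48-fold. These list calls were all lost at adjusted p = 0.86 with an estimated correlation. The call of Nip7 ended with the shared axis removed.

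The other lists were not called by camera at 6 h, with adjusted p between 0.131 and 0.866. Of 25 immediate early genes 8 rose and 1 fell, with Egr1, Ccn2, 3.84-fold, and Gadd45b, 3.19-fold, among those higher. Of 11 metallothionein and metal handling genes 3 rose, Mt1 and Mt3 by 6.11-fold and 5.5-fold. The third, Mt2A, 2.98-fold higher, was lower at log2 -0.11 with arrays scaled to equal spread, and its call ended against 150 mg/kg alone. Of 17 p53 targets 5 rose and 1 fell, with Btg1, an antiproliferative gene, 2.73-fold higher and Phlda3 2.93-fold lower. Of 24 genes of gluconeogenesis and glycogen 5 rose and 2 fell, with a median of log2 -0.02, a mean of 0.47 and a camera direction of up (adjusted p = 0.451). Of 29 cytokines and chemokines 4 rose, 3 adjusted over the list alone, and 1 fell, with Cxcl1, a neutrophil chemokine, 3.52-fold and the adhesion gene Vcam1 2.04-fold higher and Cxcl12 3.11-fold lower. Of 35 P450 genes 4 rose, among them Por, the electron donor of P450s, 3-fold, and Cyp26a1, which breaks down retinoic acid, 4.29-fold. Of 22 genes of bile acid synthesis and transport 3 fell, with Amacr and Baat, which conjugates bile acids, 2.73-fold lower. Of 20 genes of cholesterol synthesis 1 rose and 3 fell, with Insig1, which restrains that pathway, 2.16-fold higher, not called against 50 mg/kg alone, and Msmo1 and Fdft1 2.73-fold and 2.37-fold lower.

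Higher at 6 h were 4 of 31 NRF2 and glutathione genes, with Abcc3, an export pump, 1.97-fold, and 4 of 23 heat shock genes, with Hspa1a 3.89-fold. Also higher were 3 of 25 genes of endoplasmic reticulum and integrated stress, with Nupr1 and Herpud1 3.03-fold and 2.21-fold. Lower were 4 of 12 genes of sulfation and glucuronidation, with Ugt1a7c 1.85-fold. In fatty acid synthesis 2 of 19 rose and 1 fell, in the acute phase A2m rose 4.79-fold as 1 of 25, and of 17 interferon-stimulated genes 1 rose and 1 fell. Of 28 coagulation and complement genes 1 fell, C1s, 1.53-fold, and of 50 cell cycle genes 2 rose, Ccne1 and Gmnn, 1.7-fold and 1.6-fold, with 10 at an unadjusted p below 0.05 but 0 called by limma adjusted over the list alone. The calls of Hspa1a, A2m, C1s, Ccne1 and Gmnn ended with the group as a random block, and those of C1s, Ccne1 and Gmnn against 50 mg/kg alone. Without rat 3032 or 3126 that of C1s ended (log2 -0.57 and -0.56), without rat 3095 those of Ccne1 (log2 0.67) and Gmnn (log2 0.64), and without rat 3032, 3081, 3094 or 3125 that of Gmnn (log2 between 0.54 and 0.63). Of 32 proteasome genes limma called 0, with 10 at an unadjusted p below 0.05, and of 15 clock genes 1 rose, Per1, 1.84-fold, and 1 fell. Of periportal markers, 15 of 21 of which stand in another list too, 4 rose and 2 fell, among them Ass1, 1.79-fold higher, and Igfals, 1.9-fold lower. Of pericentral markers 1 of 23 rose, Oat. At most 1 gene moved in either direction among 27 macrophage, 25 lymphocyte, 24 stellate cell and fibroblast, 19 endothelial and 20 bile duct markers, with Mgp 1.92-fold higher and Slc4a2 2.45-fold lower. Adjusted over the list alone limma called 0 endothelial markers, with 7 at an unadjusted p below 0.05. Limma called 0 of 11 neutrophil and 0 of 14 red blood cell markers, with 1 and 4 at an unadjusted p below 0.05. Camera set the pericentral, endothelial, neutrophil, red cell and cytokine lists lower, while their means were log2 0.01, 0.02, 0.003, 0.01 and 0.02 and the median of the neutrophil list was 0.01.

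At 24 h, Akr7a3 was 19.3-fold higher at the higher than at the lower doses (log2 4.27 ± 0.28, SE, n = 6 rats at each level, adjusted p = 8.45e-12). Mt2A, Hspa1a, Mt1, Atf3 and Phgdh rose 15.9-fold, 14.3-fold, 12.2-fold, 12.1-fold and 11.1-fold. Stac3 fell 13.2-fold (log2 -3.72 ± 0.16), Fads1 12.7-fold and Nrep 12.2-fold, and Sez6, Kynu, an enzyme of tryptophan breakdown, and Bmf fell between 6.54-fold and 5.48-fold. Of 1717 genes called, 1134 rose and 583 fell. The count was 1052 with arrays scaled to equal spread. Of the genes that rose at 6 h, 168 rose at 24 h too, against 53 expected, and 40 fell.

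Members of several stress lists were called higher at 24 h. Of 31 measured NRF2 and glutathione genes 24 rose (median log2 0.96, camera adjusted p = 6.66e-18), among them Akr7a3, Gstp1, 5.12-fold, Nqo1, 4.7-fold, and Hmox1, 4.55-fold, and the call held at adjusted p = 0.00592 with an estimated correlation. Of 23 heat shock genes and chaperones 16 rose (adjusted p = 9.19e-14), with Hspa1a, Hsp90aa1, 6.14-fold, Hspa8, 5.12-fold, and Hsph1, 4.59-fold, and held at adjusted p = 0.0295 with an estimated correlation. Of 25 genes of endoplasmic reticulum and integrated stress 19 rose (adjusted p = 2.33e-12), with Atf3, Phgdh, Trib3, 4.77-fold, and Creld2, 4.13-fold, and held at adjusted p = 0.0228 with an estimated correlation. Of 23 ribosome biogenesis genes 17 rose (adjusted p = 1.34e-17), with Nop58, 4.86-fold, Tsr1, 3.52-fold, Nop56, 3.49-fold, and Npm1, 3.4-fold, and held at adjusted p = 0.0149 with an estimated correlation. Of 32 proteasome genes 13 rose (adjusted p = 2.14e-15), Psma5 by 1.83-fold, with the call lost at adjusted p = 0.0714 with an estimated correlation. Of 25 immediate early genes 13 rose (adjusted p = 1.29e-06), with Egr1 6.04-fold and Klf6 3.92-fold, lost at adjusted p = 0.138 with an estimated correlation. Of 11 metallothionein and metal handling genes 5 rose (adjusted p = 0.00798), with Mt3, 4.6-fold, and the transferrin receptor Tfrc, 1.73-fold, lost at adjusted p = 0.111 with an estimated correlation. Of 17 p53 targets 7 rose, and 8 adjusted over the list alone (camera adjusted p = 0.00682), with Ccng1 2.13-fold and Tigar, a regulator of glycolysis, 1.8-fold, lost at adjusted p = 0.217 with an estimated correlation.

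Members of inflammatory lists were called higher at 24 h as well. Of 29 cytokines and chemokines 8 rose and 1 fell (camera adjusted p = 0.0071, lost at adjusted p = 0.239 with an estimated correlation), with the chemokines Cxcl1, Ccl2 and Ccl7 4.67-fold, 3.85-fold and 3.19-fold higher and Cxcl12 3.16-fold lower. Of 25 acute phase genes 9 rose and 1 fell (adjusted p = 0.0219, lost at adjusted p = 0.399 with an estimated correlation), with A2m 7.62-fold, Lbp, which binds bacterial lipopolysaccharide, 3.74-fold and Orm1 2.88-fold higher. Of 17 interferon-stimulated genes 7 rose (adjusted p = 0.00417, lost at adjusted p = 0.283 with an estimated correlation), with Ifit3 4.55-fold and Usp18 3.14-fold higher.

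Members of lipid and hepatocyte lists were called lower at 24 h. Of 20 genes of cholesterol synthesis 14 fell (median log2 -1.01, camera adjusted p = 7.02e-13), with Fdft1, Cyp51, Tm7sf2 and Ebp between 3.51-fold and 2.31-fold lower, and the call held at adjusted p = 0.0487 with an estimated correlation. Of 19 genes of fatty acid synthesis 6 fell (adjusted p = 2.94e-06, held at adjusted p = 0.0487 with an estimated correlation), with Fads1 and Fads2, 5.42-fold, and Fasn, 2.88-fold. The call of Fasn ended with arrays scaled to equal spread, with the group as a random block and against 50 mg/kg alone. Of 35 P450 genes 14 fell and 1 rose (adjusted p = 6.68e-06, lost at adjusted p = 0.119 with an estimated correlation), with Cyp2c11 3.42-fold and Cyp2j3 2.49-fold lower. Of 22 genes of bile acid synthesis and transport 10 fell and 2 rose (adjusted p = 0.000111, lost at adjusted p = 0.119 with an estimated correlation), with the uptake carriers Slco1b2 and Slc10a1 3.27-fold and 2.94-fold lower and Slc27a5 3.01-fold lower. Of 34 urea cycle and amino acid genes 7 fell and 1 rose, and 8 fell adjusted over the list alone (adjusted p = 3.42e-06, lost at adjusted p = 0.138 with an estimated correlation), with Oat 3.19-fold, Otc, a urea cycle enzyme, 2.75-fold and Cdo1, which oxidises cysteine, 2.66-fold lower. Of 28 coagulation and complement genes 7 fell and 1 rose (adjusted p = 2.34e-07, lost at adjusted p = 0.124 with an estimated correlation), with complement C6 3.6-fold lower. Of 24 genes of gluconeogenesis and glycogen 6 fell and 3 rose, and 7 fell adjusted over the list alone (adjusted p = 0.0153, lost at adjusted p = 0.239 with an estimated correlation), with G6pc1 3.49-fold lower and Igfbp1, an insulin-regulated member, 5.39-fold higher. The call of G6pc1 ended against 50 mg/kg alone. Of 30 fatty acid oxidation genes 6 fell and 2 rose (adjusted p = 0.0134, lost at adjusted p = 0.348 with an estimated correlation), with Hadh 2.02-fold lower and Acaa2 2.11-fold higher.

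Of 23 pericentral hepatocyte markers, 7 of which stand in another list too, 12 fell and 1 rose at 24 h (median log2 -0.63, camera adjusted p = 2.37e-05), with Avpr1a, a vasopressin receptor, 4.06-fold, Glul 2.77-fold and Rgn 2.68-fold lower, and the call was lost at adjusted p = 0.0714 with an estimated correlation. Of 21 periportal markers 9 fell, and 10 adjusted over the list alone (median log2 -0.53, camera adjusted p = 4.22e-07), with Cyp2f4 1.93-fold lower, and the call held at adjusted p = 0.0487 with an estimated correlation. Of 27 macrophage markers 4 rose and 1 fell (median log2 -0.01, mean 0.20, camera adjusted p = 0.475), with Spp1 and Gpnmb 2.63-fold and 2.62-fold higher, and of 11 neutrophil markers 2 rose, with S100a9 3.87-fold higher (adjusted p = 0.244). The call of Spp1 ended with the compared rats alone and with the random block. Of 50 cell cycle genes 11 rose and 1 fell, and 12 rose adjusted over the list alone (adjusted p = 0.058). They included Mcm5, 3.77-fold, Mcm4, 2.37-fold, and Fen1, a nuclease of DNA replication, 2.31-fold. Of 12 genes of sulfation and glucuronidation 3 rose and 3 fell (adjusted p = 0.319), with Papss1, which makes the sulfate donor, 1.68-fold higher (probes at log2 0.17 and 1.33) and Sult1c3 3.77-fold lower. Of 15 clock genes 3 rose (adjusted p = 0.492). Of 24 stellate cell markers 1 fell (adjusted p = 0.202), and of 20 bile duct markers 1 rose, Spp1 (median log2 -0.08, mean 0.001, adjusted p = 0.319). Limma called 0 of 44 oxidative phosphorylation genes and 0 of 25 lymphocyte, 19 endothelial and 14 red blood cell markers, with 13, 4, 7 and 6 at an unadjusted p below 0.05 and camera adjusted p of 0.531, 0.514, 0.35 and 0.286.

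At 48 h, Spp1 was at least 48.9-fold and A2m at least 40.5-fold higher at the higher than at the lower doses (log2 5.61 ± 0.40 and 5.34 ± 0.55, SE, n = 6 rats at each level), both limited by the cap. Mt2A rose 19.3-fold, Gpnmb 12.2-fold, Mcm5 11.3-fold and Ube2c 11.2-fold. Stac3 fell 29.3-fold (log2 -4.87 ± 0.16, adjusted p = 1.93e-18), and Cyp2c11, Cyp3a2, Pbsn, Nrep and Zfp354a fell between 12.8-fold and 10.1-fold. Of 2137 genes called, 1429 rose and 708 fell (3322 and 3449 without a fold minimum), and the count was 1304 with arrays scaled to equal spread. Of the genes that rose at 24 h, 580 rose at 48 h too, against 93.7 expected, and of those that fell 311 fell at both times, against 23.9.

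The cell cycle list had the smallest camera p at 48 h. Of 50 measured cell cycle genes 36 rose (median log2 1.27, camera adjusted p = 5.82e-25), with Mcm5, Ube2c, the proliferation marker Mki67, 10.4-fold, and Cdk1, 9.38-fold, and the call held at adjusted p = 0.0378 with an estimated correlation. Of 31 NRF2 and glutathione genes 20 rose and 1 fell (adjusted p = 7.28e-09, held at adjusted p = 0.0378 with an estimated correlation), with Gstp1 8.62-fold, Gsta3 4.58-fold, Akr7a3 4.24-fold and Nqo1 3.63-fold higher. Of 23 ribosome biogenesis genes 8 rose (adjusted p = 7.48e-06, lost at adjusted p = 0.194 with an estimated correlation), with Nop58 2.35-fold, and of 32 proteasome genes 5 rose (adjusted p = 1.91e-07, lost at adjusted p = 0.247 with an estimated correlation), with Psmb7 2.27-fold. Of 25 immediate early genes 15 rose (adjusted p = 0.000619, lost at adjusted p = 0.29 with an estimated correlation), with Egr1 7.49-fold and Nr4a1 3.2-fold. Of 25 genes of endoplasmic reticulum and integrated stress 11 rose and 1 fell (adjusted p = 0.000421, lost at adjusted p = 0.226 with an estimated correlation), with Atf3 4.73-fold, Phgdh 4.22-fold and Ddit3 2.8-fold higher. Of 23 heat shock genes 6 rose (adjusted p = 0.00131, lost at adjusted p = 0.29 with an estimated correlation), with Hsp90aa1 2.93-fold and the chaperonin subunit Cct5 2.38-fold. Of 11 metallothionein and metal handling genes 4 rose (adjusted p = 0.0303, lost at adjusted p = 0.217 with an estimated correlation), with Mt1 6.55-fold and Mt3 2.28-fold. Of 17 interferon-stimulated genes 6 rose (adjusted p = 0.0322, lost at adjusted p = 0.352 with an estimated correlation), with Gbp2 1.85-fold higher.

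Members of lists of hepatocyte metabolism were called lower at 48 h. Of 34 genes of the urea cycle and amino acid breakdown 21 fell (median log2 -0.66, camera adjusted p = 5.64e-13), with Oat 8.8-fold, Gnmt, glycine methyltransferase, 6.24-fold, Kynu 4.3-fold and Ass1, a urea cycle enzyme, 2.56-fold lower, and the call held at adjusted p = 0.0378 with an estimated correlation. Of 24 genes of gluconeogenesis and glycogen 13 fell (adjusted p = 3.26e-07, held at adjusted p = 0.0378 with an estimated correlation), with Pck1, the rate-limiting enzyme of gluconeogenesis, 4.37-fold, G6pc1 3.78-fold and Gpt, alanine aminotransferase, 3.53-fold lower. Of 35 P450 genes 18 fell and 2 rose (adjusted p = 1.14e-07), with Cyp2c11, Cyp3a2, Cyp3a9, 5.39-fold, and Cyp1a2, 4.52-fold lower, and the call was lost at adjusted p = 0.0803 with an estimated correlation. Of 21 periportal markers 14 fell (adjusted p = 4.94e-08, held at adjusted p = 0.0378 with an estimated correlation), and of 23 pericentral markers 13 fell and 2 rose (adjusted p = 1.7e-06, held at adjusted p = 0.0456 with an estimated correlation). The pericentral member Lgals1, a galectin not restricted to hepatocytes, was 3.67-fold higher. Of 12 genes of sulfation and glucuronidation 7 fell and 1 rose (adjusted p = 0.0118, lost at adjusted p = 0.28 with an estimated correlation), with the sulfotransferases Sult1e1, Sult1c3 and Sult1c2 3.69-fold, 3.3-fold and 2.57-fold lower. Of 22 bile acid genes 10 fell and 2 rose (adjusted p = 0.000143, lost at adjusted p = 0.178 with an estimated correlation), with the carriers Slco1a1 and Slco1a4 3.88-fold and 3.79-fold lower and the sterol transporter Abcg5 3.87-fold higher. Of 28 coagulation and complement genes 10 fell and 4 rose (adjusted p = 0.000213, lost at adjusted p = 0.28 with an estimated correlation), with Proc, protein C, 2.31-fold lower and Apoa1, an apolipoprotein, 2.48-fold higher. Of 19 fatty acid synthesis genes 5 fell and 1 rose (adjusted p = 0.00396, lost at adjusted p = 0.226 with an estimated correlation), with Fads2 1.97-fold lower and Scd2 1.98-fold higher. Of 30 fatty acid oxidation genes 6 fell and 2 rose (adjusted p = 0.0107, lost at adjusted p = 0.304 with an estimated correlation), with Acadm 2.08-fold lower.

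Of 27 macrophage and monocyte markers, 4 of which stand in another list too, 12 rose at 48 h beside these falls (median log2 0.45, camera adjusted p = 9.23e-05), with Spp1, Gpnmb, Lgals3, 5.73-fold, and the Fc receptor Fcgr2b, 3.37-fold higher, and the call was lost at adjusted p = 0.217 with an estimated correlation. The other marker lists were not called by camera. Of 24 stellate cell and fibroblast markers 7 rose (adjusted p = 0.0528), with Des, desmin, 3.01-fold, Pcolce, which enhances collagen processing, 2.83-fold and Vim, vimentin, 2.13-fold higher. Of 11 neutrophil markers 3 rose, with S100a9 4.06-fold higher, of 19 endothelial markers 2 rose, with Fcgr2b and Ramp2 (adjusted p = 0.0633 for each list), and of 20 bile duct markers 2 rose, Spp1 and Anxa1, 2.59-fold (adjusted p = 0.461). The call of Ramp2, 1.63-fold higher, ended with scaled arrays, with the random block and without rat 3119 (log2 0.55). Of 25 lymphocyte markers 2 fell, Jchain and Cd79b of the B cell lineage, 1.58-fold and 1.51-fold (adjusted p = 0.304). Their calls ended with scaled arrays, and that of Cd79b, close to the fold minimum, without rat 3057, 3059, 3119, 3150 or 3151 (log2 between -0.58 and -0.48). Of 14 red blood cell markers 1 fell, Alas2, the first enzyme of heme synthesis in red cells, 1.89-fold (adjusted p = 0.195). Of 29 cytokines 7 rose and 1 fell (adjusted p = 0.0528), with Ccl2 4.23-fold and Tlr2 2.85-fold higher, and of 25 acute phase genes 7 rose and 3 fell (adjusted p = 0.265), with A2m, Lbp, 6.64-fold, and Orm1, 4.15-fold higher. Of 17 p53 targets 6 rose (adjusted p = 0.0528), with the death receptor Fas 2.84-fold and Ccng1 2.04-fold higher. Of 20 cholesterol synthesis genes 3 rose and 4 fell (median log2 0.09, mean -0.05, adjusted p = 0.802), with Sqle 2.37-fold higher and Tm7sf2 3.06-fold lower. Of 15 clock genes 3 rose, with Timeless 3.03-fold and Dbp 2.24-fold (adjusted p = 0.304). Limma called 0 of 44 oxidative phosphorylation genes, with 17 at an unadjusted p below 0.05 (camera adjusted p = 0.68).

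**Figure D3:**
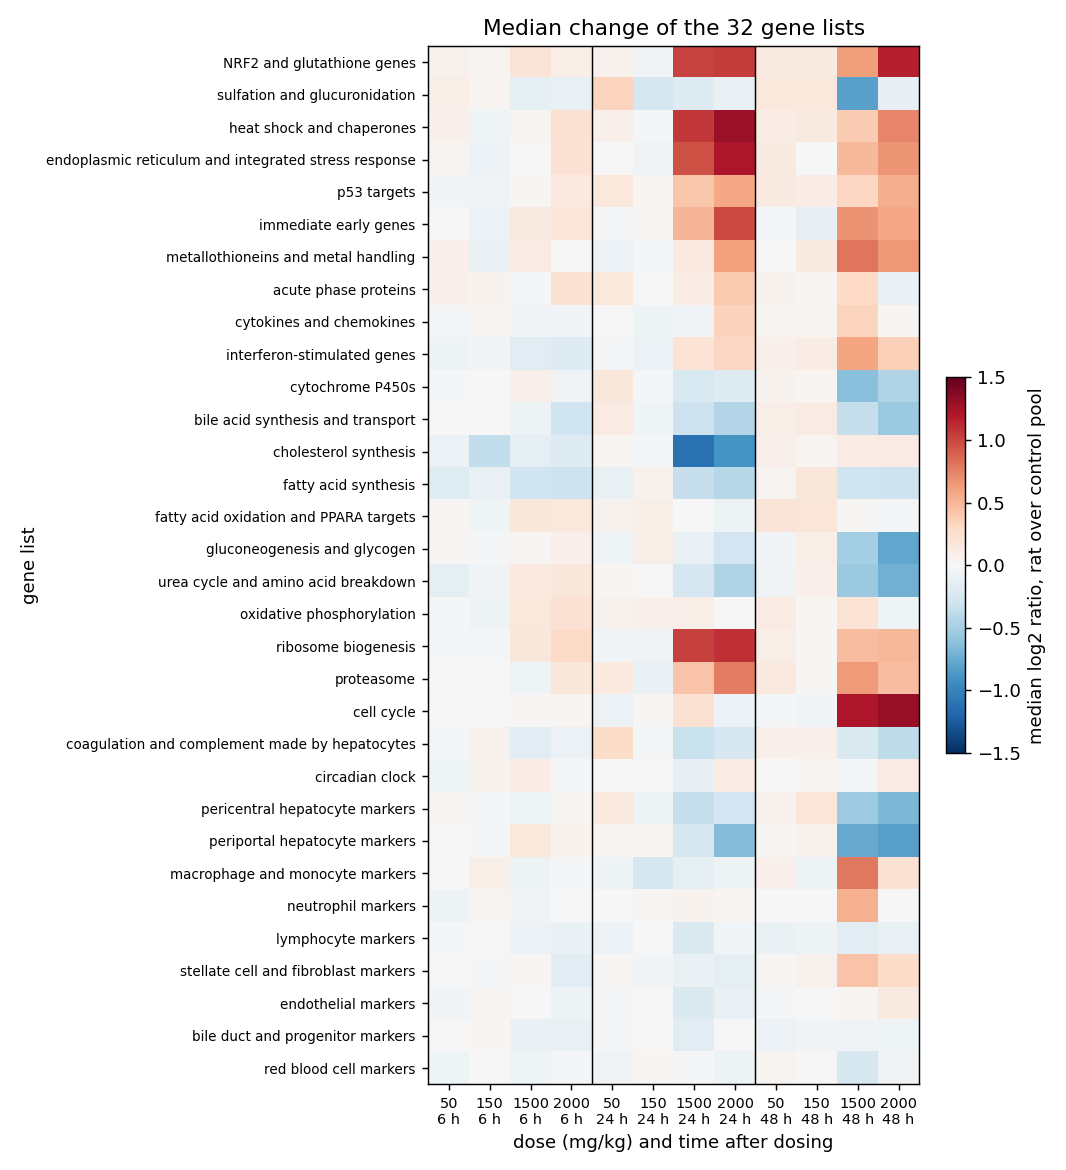
Median change from the control pool (log2) of each gene list in each group, by dose in mg/kg and time in h. At 48 h the cell cycle list had medians of 1.21 at 1500 and 1.31 at 2000 mg/kg.

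The higher doses were set against each other to ask how 2000 differs from 1500 mg/kg. At 6 h, Mt2A and Mt1 were 4.28-fold and 3.4-fold higher at 2000 mg/kg (log2 2.10 ± 0.48 and 1.76 ± 0.42, SE, n = 3 rats at each dose), and Bst2 was 2.98-fold higher. Erich1 and Ldhc were 3.1-fold and 2.36-fold lower. In all 106 genes were called, 65 higher and 41 lower. With the 6 rats alone limma called 0, with 1150 genes at an unadjusted p below 0.05, and the counts were 22 with scaled arrays, 272 over 72 arrays and 168 with the shared axis removed. The count was 38 without rat 3095, and 444, 311 and 178 without rats 3031, 3030 and 3032. The balance of directions reversed without rat 3032 (65 higher and 113 lower), 3093 (47 and 61) or 3094 (54 and 76). The call of Mt2A ended with scaled arrays and without rat 3032, 3093 or 3095 (log2 1.80, 2.09 and 2.03), that of Mt1 in these cases (log2 1.54, 1.81 and 1.74) and without rat 3094 (log2 1.74), that of Ldhc without rat 3095 (log2 -1.11), and that of Erich1 without rat 3030 or 3095 (log2 -0.97 and -1.42).

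At 24 h, Fcgr2b was 4.51-fold higher at 2000 than at 1500 mg/kg (log2 2.17 ± 0.47, SE, n = 3 rats at each dose, adjusted p = 0.0042). Lbp was 3.5-fold higher, Zfp354a 9.51-fold lower (log2 -3.25 ± 0.42), Slc2a5 4.19-fold lower (log2 -2.07 ± 0.28) and Pck1 3.66-fold lower. Of 897 genes called, 433 were higher and 464 lower (1202 and 929 without a fold minimum, 443 and 336 with the residual dye effect removed, 451 and 437 with median centring, 490 and 470 with the shared axis removed). Of 25 acute phase genes 5 were higher, and 6 adjusted over the list alone (camera adjusted p = 0.000352, lost at adjusted p = 0.617 with an estimated correlation). Of 29 cytokines 5 were higher, and 6 adjusted over the list alone (adjusted p = 0.000362, lost at adjusted p = 0.617 with an estimated correlation), and of 24 gluconeogenesis genes 5 were lower (adjusted p = 0.00338, lost at adjusted p = 0.617 with an estimated correlation). Macrophage markers were higher in 3 of 27 (adjusted p = 0.0464, lost at adjusted p = 0.684 with an estimated correlation). The count was 89 with scaled arrays, where the calls of Fcgr2b, Lbp, Zfp354a and Slc2a5 ended, and 17, 3 higher and 14 lower, with the 6 rats alone, where those of Fcgr2b, Lbp, Zfp354a and Pck1 ended. It was 564 without rat 3107 and 1265, 773 higher and 492 lower, without rat 3105, and that of Lbp ended without rat 3020 (log2 1.19).

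At 48 h, Gsta3 was 6.29-fold higher at 2000 than at 1500 mg/kg (log2 2.65 ± 0.36, SE, n = 3 rats at each dose, adjusted p = 7.15e-05), and Erich1, Akirin2 and Ldhc were 5.64-fold, 4.98-fold and 3.55-fold higher. Trem2, a receptor of macrophages, and the fatty acid binding protein gene Fabp4 were 3.81-fold and 4.64-fold lower (log2 -1.93 ± 0.21 and -2.22 ± 0.30), the neutrophil gene S100a9 5.05-fold lower, and Slc6a6 3.84-fold lower. Of 31 NRF2 and glutathione genes 13 were higher and 1 lower (camera adjusted p = 1.29e-05, lost at adjusted p = 0.615 with an estimated correlation). Of 27 macrophage markers 8 were lower and 1 higher, and 9 were lower adjusted over the list alone (adjusted p = 0.00144, lost at adjusted p = 0.649 with an estimated correlation), and of 11 neutrophil markers 3 were lower (adjusted p = 0.0229, lost at adjusted p = 0.615 with an estimated correlation). Of 44 oxidative phosphorylation genes 3 were lower (adjusted p = 1.03e-08, lost at adjusted p = 0.615 with an estimated correlation). Of 935 genes called, 360 were higher and 575 lower (1351 and 1217 without a fold minimum), while with scaled arrays 219 were called, 112 higher and 107 lower. With the 6 rats alone 382 were called, 244 higher and 138 lower, so that the balance of directions reversed, without Gsta3, Fabp4 and S100a9. The count was 554 without rat 3008 and 610 without rat 3007, where the call of S100a9 ended (log2 -1.90).

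Changes over time were compared at the higher doses, as the mean of 1500 and 2000 mg/kg at 24 h minus that at 6 h, and at 48 h minus 24 h, each rat being measured at 1 time. From 6 to 24 h, Akr7a3 rose 17.3-fold (log2 4.11 ± 0.28, SE, n = 6 rats at each time), Atf3 8.13-fold, Phgdh 6.81-fold, Creld2 6.25-fold, Gstp1 5.53-fold and the transcription factor gene Bhlha15 5.27-fold. Zfp354a fell 19.3-fold (log2 -4.27 ± 0.30, adjusted p = 2.66e-11), Sds 11.9-fold, Sez6 7.34-fold, Cyp3a2 7.12-fold, Got1 6.66-fold and G6pc1 6.54-fold. Of 31 NRF2 and glutathione genes 21 rose and 1 fell (camera adjusted p = 4.02e-13, held at adjusted p = 0.0331 with an estimated correlation). Of 23 heat shock genes 15 rose, and of 34 urea cycle and amino acid genes 16 fell (adjusted p = 2.74e-12 and 1.8e-09, lost at adjusted p = 0.0606 and 0.0932 with an estimated correlation). In all 998 genes rose and 756 fell (2757 and 2740 without a fold minimum), 1754 together, against 950 with arrays scaled to equal spread.

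From 24 to 48 h at the higher doses, Spp1 rose at least 26.4-fold (log2 4.72 ± 0.40, SE, n = 6 rats at each time), limited by the cap at 48 h, and the mitotic genes Ube2c, Cdkn3, Ska1, Cdk1 and Mki67 rose between 12.4-fold and 9.03-fold. Zfp354a fell 9.2-fold (log2 -3.20 ± 0.30), Hspa1a 6.16-fold, Igfbp1 4.2-fold, Cyp3a9 4.06-fold, Cyp2e1 3.94-fold and Ifrd1 3.92-fold. Of 50 cell cycle genes 32 rose, of 20 cholesterol synthesis genes 13 rose, and of 27 macrophage markers 14 rose, with camera adjusted p of 6.26e-25, 1.48e-15 and 5.04e-08. These calls were lost at adjusted p = 0.0565, 0.0662 and 0.154 with an estimated correlation. Of 23 heat shock genes 9 fell and of 23 ribosome biogenesis genes 8 fell (adjusted p = 1.7e-05 and 1.15e-07, lost at adjusted p = 0.249 and 0.154 with an estimated correlation). In all 989 genes rose and 582 fell (2637 and 3101 without a fold minimum, 920 and 355 with the residual dye effect removed), 1571 together, against 729 with arrays scaled to equal spread and 970 with the group as a random block.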

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

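The tests of the explanations for the 3 patterns weighed here were chosen after the result was seen, apart from the test of control pools for the macrophage markers, which was chosen before it was seen, as were the splits of single rats. The splits of whole groups and the alternatives for differences between times were chosen after it was seen. The choices of groups, contrasts, lists and genes were made before the data were examined.

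The effect of dose level, 1500 and 2000 against 50 and 150 mg/kg, differed between times by an interaction term in limma. It differed between 24 and 6 h in 2260 genes, between 48 and 24 h in 1118 and between 48 and 6 h in 2421. With the group as a random block, which allows for pool differences of average size, these were 901, 220 and 1399. The first had 432 higher and 469 lower, against 1136 and 1124. For 97 genes, 42 with the random block, it turned from 6 to 48 h, being called at both times with opposite sign and in the difference. Zfp354a changed by log2 -6.47 ± 0.42 (SE) from 3.14 at 6 h to -3.33 at 48 h (adjusted p = 1.62e-11). Sds changed by log2 -4.30 ± 0.48 from 3.11 to -1.20 (adjusted p = 1.45e-07), with its fall at 48 h not called with arrays scaled to equal spread, with the compared rats alone, with the group as a random block or against 50 mg/kg alone. Oat, an aminotransferase of ornithine, changed by log2 -4.07 ± 0.28 from 0.93 to -3.14 (adjusted p = 2.98e-11). With the random block these 3 differences had adjusted p = 8.6e-05, 0.000201 and 3.38e-08. Of 32 lists camera called 18, 15 and 15 for the 3 differences, and 0, 1 and 3 held with an estimated correlation. From 24 to 48 h it was the cell cycle list (median log2 0.87, adjusted p = 0.0269 with an estimated correlation), while cholesterol synthesis, at 0.67, was among those lost (adjusted p = 0.0825 with an estimated correlation). From 6 to 48 h they were cell cycle (1.21), amino acid breakdown (-0.96) and gluconeogenesis (-0.61), each at adjusted p = 0.0283. The difference between 2000 and 1500 mg/kg differed between 24 and 6 h in 1007 genes and between 48 and 24 h in 2068, 950 higher and 1118 lower. With arrays scaled to equal spread these were 89 and 284, and with the compared rats alone 26 and 1395, the latter with 864 higher and 531 lower. The 2068 fell to 1360 with the dye effect removed and to 1414 without rat 3008. Each group has its own control, so pools cannot be separated from dose here. Of the lists camera called 7 from 24 to 48 h, acute phase (median log2 -0.79), cytokines (-0.70), macrophage (-0.62), proteasome (-0.41), coagulation (-0.29), NRF2 (0.40) and cell cycle (0.32), all lost at adjusted p = 0.483 or above with an estimated correlation.

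Splits of the rats into other groups tested whether chance could give such counts in a fit of the compared rats with 2 arms. For the dose levels, 1 of 100 splits drawn, the real split itself, gave as many genes at each time. Chance in how single rats were grouped can be excluded for the 1248 genes at 6 h, where the highest other of the 100 gave 0, for the 1513 at 24 h, where it gave 1, and for the 2029 at 48 h, where it gave 2. It can also be excluded for the change from 6 to 24 h, with 1455 genes and 0 in the highest other split, and from 24 to 48 h, with 1239 genes and 9. The rats of a group share a pool, with a correlation within groups of 0.283, and these splits moved single rats between pools, so they leave out differences between pools. The 3 splits of whole groups are too few for a share under 0.05. The highest other of these gave 52, 10 and 2 genes for the dose levels at 6, 24 and 48 h, 0 for 6 to 24 h and 49 for 24 to 48 h. With the group as a random block the counts were 932, 1389 and 1792 for the dose levels, and 1441 and 970 for the changes in time. For 2000 against 1500 mg/kg the 10 splits of the 6 rats are too few for a share under 0.05. At 6 h 10 of 10 splits gave as many as the real 0 genes, with 1150 genes at an unadjusted p below 0.05 in limma with those rats alone. At 24 h 1 of 10 gave the real 17, with 0 in the highest other, and at 48 h 1 of 10 gave the real 380, with 1.

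More genes were called at 50 than at 150 mg/kg. At 24 h, with 614 and 25 genes, 52.8% of the genes called at 50 mg/kg had the same sign at 150 mg/kg, which argues against an effect of acetaminophen that grows from 50 to 150 mg/kg. Removal of the residual dye effect, a part that differs in strength between the arrays of a rat, left 497, which argues against that as the whole cause. An axis of expression shared by several groups may account for the count at 24 h, since 116 were called after removal of the first axis of the 150 mg/kg groups, which holds no 50 mg/kg rat, and 54 after removal of that of all other lower-dose groups. Neither removal tells a technical axis from a response to acetaminophen, and the rats at 1500 mg/kg and 48 h correlated with the latter axis at 0.438 to 0.538. At 6 h the same tests gave 55.7%, 240, 245 and 264 genes, which argues against each of these explanations there. Set against 2000 mg/kg, 66.6% of the genes higher and 90.9% of those lower at 50 mg/kg and 24 h had the same sign, with 101 called higher at both doses against 37.4 expected, 27 called higher at 50 and lower at 2000 mg/kg, and 13 lower at both against 11.2. At 6 h it was 77.1% of the higher, with 79 at both against 12.1, and 60% of the 10 lower. At 48 h it was 88.2% and 92.4%, with 215 higher at both against 48.7 and 224 lower against 27.9. At 24 and 48 h these values go as well with the shared axis, with which the 2000 mg/kg rats correlated at 0.157 to 0.314 and 0.449 to 0.565, as with acetaminophen. At 48 h, with 684 and 256 genes, 92% had the same sign at 150 mg/kg. There 43 were called at each dose after removal of the axis, and 528 and 267 after removal of the dye effect. An effect that grows from 50 to 150 mg/kg stays open at 48 h too. The difference in counts also depended on the scale of the arrays. With arrays scaled to equal spread 588 and 565 genes were called at 24 h and 562 and 474 at 6 h, though such scaling by construction raises the values of arrays with a small spread. With the 3 rats of a group alone limma called 0 and 4 at 24 h, with 4515 and 2908 genes at an unadjusted p below 0.05, and 206 and 0 at 6 h, with 3879 and 3789. A difference in array spread, dose itself, a response of low dose alone and differences between controls, which the titles name differently for 150 mg/kg at 6 and 24 h, stay open.

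Of 69 P450 and amino acid genes 39 were called lower and 2 higher at 48 h at the higher doses. The list call of the P450 genes was lost at adjusted p = 0.0803 with an estimated correlation, and that of the amino acid genes held at adjusted p = 0.0378. Of the 39, 36 were called lower with the group as a random block. This sets the same correlation for all genes, so control pools stay open. If a lower hepatocyte share raised all other cells alike, their markers would rise alike. The macrophage list lay above the lymphocyte list by at least log2 0.241 in each of the 6 rats, though 4 of 27 macrophage markers stand in another list. The medians of single rats were log2 0.23 to 1.05 for macrophage, 0.212 to 0.433 for stellate, 0 to 0.207 for endothelial, -0.16 to 0.0062 for bile duct and -0.208 to -0.0105 for lymphocyte markers. This argues against a lower share as the whole cause, while the rise of stellate markers in all 6 rats goes with a part of it. Loss of pericentral hepatocytes alone was tested on 11 periportal and 19 pericentral markers outside the P450 and amino acid lists. The periportal median was log2 -0.648 or lower and below the pericentral one in each rat. With full lists rat 3007 reversed (log2 -0.51 and -0.563). That loss alone leaves the periportal fall unexplained. Lower P450 and amino acid gene expression in hepatocytes was not tested. A lower share of all or pericentral hepatocytes and a change of macrophages or stellate cells stay open.

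Of 37 macrophage and neutrophil markers 10 were called lower and 1 higher at 2000 than at 1500 mg/kg at 48 h, and both list calls were lost, at adjusted p = 0.649 and 0.615 with an estimated correlation. The medians of single rats did not overlap between the doses for neutrophil markers, and did for macrophage markers (log2 0.35 to 1.05 and 0.23 to 0.434). Stellate markers (0.377 to 0.433 and 0.212 to 0.297) and acute phase genes (0.103 to 0.524 and -0.157 to -0.0382) lay lower at 2000 mg/kg too, without overlap, as did oxidative phosphorylation genes. NRF2 genes, clock genes and red blood cell markers (-0.301 to -0.18 and -0.163 to -0.033) lay higher without overlap. Chance gives such a gap for 10% of lists with 3 rats against 3. After removal of the residual dye effect 9 macrophage and neutrophil members were called lower, which argues against that effect. A higher share of hepatocytes at 2000 mg/kg stays open. The list of coagulation and complement genes made by hepatocytes had a median difference of log2 -0.225, but the medians of single rats overlapped (-0.436 to 0.0537 and -0.572 to -0.213), as did those of the P450, endothelial, bile duct and lymphocyte lists. The control pools cannot be told apart from dose, since the macrophage list differed by up to log2 -0.18 between 150 and 50 mg/kg at 24 h, against -0.29 between the higher doses at 48 h, and each dose had its own control. A slower or smaller macrophage response at 2000 mg/kg may be the cause and stays open, as does a difference in time course between doses.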

How the results depend on the processing

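Which results depend on the processing was tested with alternatives, of which the removal of the dye effect, of the shared axis or of the axis of the 150 mg/kg groups each lower dose alone and all those for differences of an effect between times were chosen after seeing the data. Counts are given as 50, 150, 1500 and 2000 mg/kg, then dose levels, then 2000 against 1500 mg/kg, where they moved by over 1.5 times. With arrays scaled to equal spread, they were 562, 474, 600, 903 and 22 (2000 against 1500 mg/kg) at 6 h, 565 (150 mg/kg), 940, 1149, 1052 (dose levels) and 89 at 24 h, and 551 (150 mg/kg), 1923, 2447, 1304 (dose levels) and 219 at 48 h, with 950 for 6 to 24 h and 729 for 24 to 48 h. Mt2A turned to log2 -0.11 in the dose levels at 6 h. With 72 arrays as observations 51 and 59 were called at 150 mg/kg at 6 and 24 h and 272 for 2000 against 1500 mg/kg at 6 h. With the compared rats alone, which leaves fewer degrees of freedom, limma called 0 at 150 mg/kg and 59 at 1500 mg/kg at 6 h, 0 at 50 and 4 at 150 mg/kg at 24 h, 0 at 50 and 0 at 150 mg/kg at 48 h, and 0, 17 and 382 for 2000 against 1500 mg/kg at 6, 24 and 48 h. The comparisons with 0, in the order given, had 3789, 4515, 4928, 4394 and 1150 genes at an unadjusted p below 0.05. Without a fold minimum, which by construction adds small changes, counts were 655, 5044 and 5564 (50, 1500 and 2000 mg/kg), 5675 (dose levels) and 212 at 6 h, 3210, 51, 6296, 8123, 5513 and 2131 at 24 h, 3201, 1141, 9793, 9375, 6771 and 2568 at 48 h, 5497 for 6 to 24 h and 5738 for 24 to 48 h. With the group as a random block they were 932 for dose levels at 6 h and 970 for 24 to 48 h. With the shared axis removed they were 13 and 800 (150 and 1500 mg/kg), 807 (dose levels) and 168 at 6 h, 54 (50 mg/kg) at 24 h, and 43, 43, 2124 and 2243 at 48 h. With the axis of the 150 mg/kg groups removed they were 116 and 152 (62 higher and 90 lower) at 50 mg/kg at 24 and 48 h, and Mt2A at 50 mg/kg and 48 h turned to log2 1.33. Leaving out 1 rat at a time gave 1 to 2 at 150 mg/kg and 493 to 2438 at 1500 mg/kg at 6 h, 399 to 913 at 50 mg/kg and 3 to 12 at 150 mg/kg at 24 h, 141 to 269 at 150 mg/kg at 48 h, and 38 to 444, 564 to 1265 and 554 to 1119 for 2000 against 1500 mg/kg at 6, 24 and 48 h, with Lcn2 at 1500 mg/kg and 24 h between log2 -0.021 and 1.34. Apart from the fold minimum, the cause was not tested. All 20 counts stayed within 1.5 times with median centring, robust moderation, dim probes left out, probes valued on all arrays, single probes and the dye effect removed, though the last gave 348 higher and 149 lower at 50 mg/kg and 24 h, against 362 and 252, and 371 and 157 at 48 h, against 380 and 304, and 920 and 355 for 24 to 48 h, against 989 and 582. Differences of the dose effect between times fell to 901 (24 against 6 h), 220 (48 against 24 h), 1399 (48 against 6 h) and 42 (turned) with the random block, and to 738 for 48 against 24 h with scaled arrays. Removal of the dye effect left 904 higher and 993 lower for 24 against 6 h, against 1136 and 1124. Those of 2000 against 1500 mg/kg fell to 89 with scaled arrays and 26 with the compared rats alone for 24 against 6 h, and to 284 with scaled arrays and 1360 without the dye effect for 48 against 24 h. Of 615 values of named genes 548 kept direction and call with scaled arrays, 580 without the shared axis and 539 with the compared rats alone, as did 263 of 321 with the random block and 4601 of 4812 with a rat left out. Of 352 list tests 163 were called with the preset correlation, and with an estimated correlation 20 of these held and 143 were lost. Signal over background was not used here, so calls among dim probes are limited in a way that could not be measured.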

Other observations

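No test in this part was planned before the data were seen.

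The first axis of expression over the lower-dose groups held 38% of their sum of squares, and 3 of these 6 groups shared it. Over genes, which are not independent replicates, each rat correlated with the axis of the other lower-dose groups at 0.546 to 0.696 at 50 mg/kg and 24 h, 0.583 to 0.683 at 50 mg/kg and 48 h, and 0.351 to 0.671 at 150 mg/kg and 48 h. It was -0.218 to 0.0487 at 50 mg/kg and 6 h. At 150 mg/kg it was -0.331 to -0.17 at 6 h and -0.316 to 0.0326 at 24 h. At 1500 and 2000 mg/kg and 48 h it was 0.438 to 0.538 and 0.449 to 0.565.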
